A study of Caenorhabditis elegans with 12 samples.

How the data were processed

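Total RNA from lysates of Caenorhabditis elegans of 2 strains was labelled with biotin as cRNA and hybridised to 12 arrays, per the labels' protocols. The deposited values are array intensity on a linear scale, 1 MAS5 signal per probe set and array, and MAS5 is named in the submitters' processing notes. Its version and settings are not given in the sources used here. The authors' scaling was visible in the values: the 2% trimmed mean was 500.1 on every array, so the deposited scaling was kept. The table held 22625 probe sets with no missing value and none at or below 0, the highest being 23879.9. MAS5 subtracts a local background, so low signals are noisy and a ratio between low signals can be inflated, which the floor below limits.

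Arrays were grouped by the code in their title, which gave 4 groups of 3, and the source name gave the strain. No label ties a code to heat shock, so no array was called heat shocked or unheated, and no array's treatment was read from its values. The array titled 2_2 (2) shares its set number with another array of code 2, while set 3 has no array of code 2, and its set is treated as uncertain. The design text calls the replicates biological.

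Values under the 10th percentile of all values, a signal of 16.7, were raised to it and log2 was taken. Of the values of tested probe sets 0.0291% were at the floor. The 77 control probe sets were left out, and a probe set was tested if its signal was above its array's median on at least 3 of 12 arrays, which left 12328. A linear model with 4 groups was fitted with limma 3.58.1 (lmFit and eBayes with an intensity trend) in R 4.3.3, with 8 residual degrees of freedom and 4.87 prior degrees of freedom. The groups shared 1 estimate of the spread. All tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the tested probe sets of each comparison, and an adjusted p under 0.05 was a call. Fold changes are differences of mean log2 values, and the mean ± SD of signals is on the linear scale. Where all arrays of a group were at the floor, the fold is given as a lower bound.

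The comparisons were code 2 with code 1, code 4 with code 3, both HLH codes with both marker codes, each HLH code with each marker code, and the interactions under both matchings of codes. To test whether a code difference had a different size in the strains without knowing the matching, the larger p of the 2 interactions was taken for each probe set. The code differences of the strains share no array. These choices, the gene lists, the rule for naming genes and all alternatives but one were fixed before the data were examined.

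Probe sets were named from the platform's annotation, in which 20766 have 1 gene, 887 several and 972 none listed. Symbols of 20701 probe sets were updated through their gene ID with the gene table of assembly WBcel235, and 65 kept the platform's name. The build behind the probes is not given in the sources used here, so the table served only for names and for the order of neighbouring genes. No gene was named from a probe set of several genes. For gene lists a gene was represented by its brightest single-gene probe set, which gave 9418 genes.

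For the comparisons within strains and between strains over both codes, the named genes are, among called probe sets of 1 gene whose arrays did not overlap between the sides, the 10 with the largest rise and the 10 with the largest fall, 1 probe set per gene, the one with the smallest p. The rule also covered all measured members of the transgene and known Twist/E target lists, and of each other list the 2 to 4 members with the smallest p. Of the other lists, members are printed for only part of the lists and comparisons. At single codes between strains the 5 largest changes each way could be named, and for differences between code differences the 6 largest each way.

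The 29 gene lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. They were transgene genes, known Twist/E targets, M lineage and mesoderm regulators, bHLH factors, small and inducible heat shock proteins, constitutive cytosolic chaperones, ER stress, mitochondrial chaperones, oxidative stress and detoxification, metal response, proteasome and ubiquitin, ribosomal proteins, translation factors, histones, cell cycle and replication, immune response, F-box family, ubiquitin ligase adaptors and intracellular pathogen response, lipid metabolism, body wall muscle, pharynx, intestine, hypodermis and cuticle, collagens, moulting, neurons, oogenesis and germline, sperm and embryo. Some genes are on more than 1 list, hlh-8 and egl-15 being on both the transgene and target lists.

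Whether set numbers pair the arrays was decided before the fits were compared, by asking that every pair with the same number correlate. Deviations from the group means were correlated between arrays, without the array titled 2_2 (2). All 15 pairs with the same set number had r of 0.27 to 0.79, while the 30 pairs with different numbers ran from -0.69 to 0.40, so the numbers, which come from the titles, pair the arrays. The main fit nevertheless has no block, so differences between sets enter its estimate of the spread. With the block more probe sets passed in most comparisons, such as 1731 against 335 between strains. The values with the set number as a block, with the array titled 2_2 (2) left out, are given where they change a call or move a count by over 1.5 times. Replicates of a group were compared for repeats of 1 hybridisation. Spearman's rho across probe sets was 0.881 to 0.959, and at most 0.06% of values were identical, so none were merged.

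The model was tested on simulated data with independent noise, no set difference and 12328 probe sets, 100 of them changed 2-fold and 100 changed 4-fold. In the comparison of codes 1 and 2, it recovered 62 of 100 genes changed 2-fold and 100 of 100 changed 4-fold, with 7 false calls among 169. For codes 3 and 4 it recovered 53 and 97 of 100, with 2 false calls among 152, and between strains 92 and 99 of 100, with 10 false calls among 201.

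Alternatives were no filter, a filter at the 75th percentile, a floor at the 25th percentile, no floor, quantile normalization, median scaling, eBayes with no trend or with robust estimation, only the groups compared in the fit, the set number as a replicate block with the array titled 2_2 (2) left out, in set 3 or in set 2, that array averaged with its namesake, and each of 12 arrays left out in turn. For lists they also included an estimated correlation and the mean of a gene's probe sets. Leaving out the 4 arrays of set 2 was chosen after the data were seen. Figures were drawn with matplotlib 3.10.9.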

Results

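Gene expression was measured in the nematode Caenorhabditis elegans on 12 single-colour oligonucleotide arrays whose probe sets carry Affymetrix identifiers, each hybridised with biotin-labelled cRNA made from total RNA. The arrays came from 2 strains with 6 arrays each. The strain called the HLH strain here carried the reporter egl-15::gfp, constructs labelled pHS::hlh-8 and pHS::hlh-2, and the transformation marker pRF4. The gene hlh-8 encodes the nematode Twist protein, and hlh-2 encodes its E/Daughterless partner. The strain called the marker strain carried the reporter and pRF4 alone. The design text states that both strains were studied with and without heat shock in 3 biological replicates. Array titles give a set number from 1 to 3 and a code from 1 to 4, with codes 1 and 2 in the HLH strain and codes 3 and 4 in the marker strain, 3 arrays per code. The labels do not state which code was heat shocked, nor which code of one strain had the same treatment as which code of the other, so all values are given by code. The number of arrays limits the precision.

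The first comparison asked which transcripts differed between the 2 codes of the HLH strain. The small heat shock protein genes hsp-16.41 and hsp-16.2 were higher at code 2 than at code 1. The mean signal of hsp-16.41 was 84 ± 49 at code 1 and 4756 ± 487 at code 2 (SD, n = 3), and that of hsp-16.2 was 213 ± 41 and 3018 ± 972 (SD, n = 3). The transgene gene hlh-8 was also higher at code 2, with 958 ± 352 at code 1 and 4444 ± 568 at code 2 (SD, n = 3). For hsp-16.41 the log2 difference was 6.06 ± 0.45 (SE), a 66.5-fold difference with an adjusted p of 7.9e-05 in limma. It was 3.79 ± 0.38 (SE) for hsp-16.2, adjusted p = 0.00092, and 2.27 ± 0.24 (SE) for hlh-8, adjusted p = 0.00098. The other 2 called probe sets, with log2 differences of 3.12 and 4.06, each represent 2 annotated genes, both of which are on the list of small and inducible heat shock proteins. Without the filter on dim probe sets, the one with 4.06 had an adjusted p of 0.068. In all, 5 of 12328 tested probe sets passed an adjusted p of 0.05, all 5 higher at code 2 in 3 of 3 arrays against 3 of 3, a separation that has a share of 0.1 by chance for a single probe set. An unadjusted p under 0.05 was found for 284, fewer than the share of 0.05 that chance alone would give on average. Differences between sets enter the spread in this fit, so its p-values can be too large and calls can be missed.

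The partner gene hlh-2 did not pass between codes 1 and 2, with mean signals of 757 ± 268 and 1001 ± 439 (SD, n = 3) and a log2 difference of 0.38 ± 0.35 (SE). The log2 difference was 0.17 ± 0.18 (SE) for rol-6, a cuticle collagen gene, and 0.17 ± 0.25 (SE) for egl-15, an FGF receptor gene. It was 0.02 ± 0.29 (SE) for arg-1, a known target of the Twist and E proteins, and all 3 had an adjusted p of 1. The signal of arg-1 was low, with means of 165 to 188 at the 4 codes, while array medians ran from 180.3 to 208. That arg-1 did not pass, here and in the comparisons below, is therefore weak evidence against a response. A further known target, ceh-24, lay below the filter on dim probe sets and was not tested. Its mean signals at the 4 codes lay between 59 and 113, with SDs of 23 to 68 (n = 3).

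Of 11 measured small and inducible heat shock genes, 2 rose from code 1 to code 2 in the HLH strain and 4 passed when adjusted over the list alone. The 2 further members were hsp-70, with a log2 difference of 1.68 ± 0.33 (SE), and hsp-17, with 0.87 ± 0.19 (SE). The list was shifted upwards in limma's camera test, adjusted p = 2.6e-08 with the preset correlation and adjusted p = 0.027 with an estimated correlation. Its median log2 difference was 0.05 and its mean 1.15, with 8 genes higher and 3 lower. A few large differences thus carried the shift, and the list as a whole did not move. None of the 22 genes of the endoplasmic reticulum stress list passed over all probe sets, and 2 passed when adjusted over the list alone. These were hsp-4, a BiP chaperone gene, at 1.30 ± 0.27 (SE) and ckb-2 at 0.88 ± 0.21 (SE). That list was shifted upwards with an adjusted p of 4.3e-06, and adjusted p = 0.027 with an estimated correlation. The transgene list, of which 1 of 4 genes rose, had adjusted p = 3.5e-05 and adjusted p = 0.038 with an estimated correlation. The list of known Twist/E targets, of which 1 of 3 rose, had adjusted p = 0.00025 and adjusted p = 0.036 with an estimated correlation. In both lists that gene was hlh-8, which the HLH strain carried as a construct. The targets egl-15 and arg-1 were at 0.17 and 0.02, so the target list result says nothing about targets beyond hlh-8. Members of other lists passed between codes 1 and 2 when adjusted over the list alone. They were the desaturase genes fat-5 at 1.12 ± 0.30 (SE) and fat-6 at 0.61 ± 0.15 (SE), the co-chaperone gene dnj-13 at -0.85 ± 0.15 (SE), ugt-13 at 0.94 ± 0.23 (SE) and skr-4 at 0.76 ± 0.21 (SE).

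Further lists shifted between codes 1 and 2 with the preset correlation, and none of their members passed over all probe sets. The ribosomal protein list lay higher at code 2, with a median log2 difference of 0.13 over 74 genes and adjusted p = 1.6e-10, but adjusted p = 0.68 with an estimated correlation and adjusted p = 0.92 after quantile normalization. The cell cycle and replication list lay lower, median -0.17 over 25 genes, adjusted p = 5.1e-05, and adjusted p = 0.23 with an estimated correlation. The oogenesis and germline list lay lower, median -0.14 over 29 genes, adjusted p = 0.00011, and adjusted p = 0.41 with an estimated correlation. The translation factor list lay lower, median -0.09 over 35 genes, adjusted p = 0.042, with adjusted p = 0.79 with an estimated correlation and adjusted p = 0.63 with the set number as a block. With the block, 4 lists passed that did not pass without it. Constitutive cytosolic chaperones (adjusted p = 0.075, blocked 0.00063), hypodermis and cuticle (0.52, blocked 0.00046) and collagens (0.30, blocked 0.0026) lay higher at code 2, and without the block the last 2 turned lower after quantile normalization, adjusted p = 0.47 and 0.92. Neurons lay lower (0.29, blocked 0.0073), and none of the 4 passed with an estimated correlation, blocked adjusted p = 0.48, 0.48, 0.58 and 0.48. Of the lists passing with the block, ER stress held with an estimated correlation (blocked adjusted p = 0.045), while inducible heat shock (0.35), transgene (0.17) and known target (0.38) lists did not.

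The second comparison asked the same question within the marker strain. The genes hsp-16.41, hsp-16.2 and hsp-70, which encodes an inducible chaperone, were higher at code 4 than at code 3. The mean signal of hsp-16.41 was 66 ± 35 at code 3 and 4718 ± 867 at code 4 (SD, n = 3), a log2 difference of 6.26 ± 0.45 (SE) or 76.7-fold, with an adjusted p of 5.3e-05 in limma. For hsp-16.2 it was 133 ± 63 and 3414 ± 1399 (SD, n = 3), a log2 difference of 4.68 ± 0.38 (SE), adjusted p = 0.00011. For hsp-70 it was 83 ± 22 and 466 ± 167 (SD, n = 3), a log2 difference of 2.45 ± 0.33 (SE), adjusted p = 0.011. The remaining called probe sets each represent 2 annotated genes, both on the inducible heat shock list. Their log2 differences were 4.86, 3.51, 3.51 and 3.50, with adjusted p of 0.00019, 0.00017, 0.012 and 0.011. All 7 called probe sets were higher at code 4, with no overlap between the arrays of the 2 codes. An unadjusted p under 0.05 was found for 268, again fewer than chance alone would give on average. The calls of hsp-70 and of the 2 several-gene probe sets with adjusted p of 0.012 and 0.011 were lost without the filter, with adjusted p of 0.18, 0.27 and 0.27, and with only the 2 groups compared in the fit, with 0.20, 0.096 and 0.14. These 3 calls were also lost, and the count was 4, when marker code 4 replicate 1, marker code 3 replicate 3 or marker code 4 replicate 3 was left out, and the 2 several-gene calls among them were lost without marker code 3 replicate 2, adjusted p = 0.052 for each.

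In the marker strain the transgene genes did not pass between codes. The signal of hlh-8 was 144 ± 9 at code 3 and 161 ± 36 at code 4 (SD, n = 3), a log2 difference of 0.14 ± 0.24 (SE). The log2 difference was -0.02 ± 0.35 (SE) for hlh-2, 0.03 ± 0.18 (SE) for rol-6, -0.17 ± 0.25 (SE) for egl-15 and 0.13 ± 0.29 (SE) for arg-1, each with an adjusted p of 1. Of 11 inducible heat shock genes 3 rose and 4 passed when adjusted over the list alone, the further one being hsp-17 at 0.93 ± 0.19 (SE), and the list was shifted upwards with an adjusted p of 1.3e-13, and adjusted p = 0.010 with an estimated correlation. None of 22 ER stress genes passed over all probe sets and 1 passed when adjusted over the list alone, hsp-4 at 1.65 ± 0.27 (SE), and the list was shifted upwards with an adjusted p of 3.5e-06, and adjusted p = 0.018 with an estimated correlation. The constitutive cytosolic chaperone list lay higher, median 0.29 over 23 genes, adjusted p = 3.6e-06, and adjusted p = 0.19 with an estimated correlation. In that list the co-chaperone gene dnj-13 passed when adjusted over the list alone, at -0.74 ± 0.15 (SE), as it did in the HLH strain. In the neuron list, which as a whole did not pass, adjusted p = 0.58, eat-4, a vesicular glutamate transporter gene, passed when adjusted over the list alone, at -0.70 ± 0.17 (SE). The lipid metabolism list, in which fat-5 and fat-6 passed when adjusted over the list alone in this strain as in the HLH strain, lay higher, median 0.12 over 28 genes, adjusted p = 0.00052, and adjusted p = 0.060 with an estimated correlation. The ribosomal protein list lay higher, median 0.09, adjusted p = 0.00042, with adjusted p = 0.99 with an estimated correlation and adjusted p = 0.82 after quantile normalization.

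With the set number as a block, the count in the marker strain was 19, with 15 higher and 4 lower at code 4, and all 7 probe sets called without the block were among them. The genes called with the block alone included hsp-4 at a log2 difference of 1.65, the small heat shock gene hsp-17 at 0.93, the cytosolic chaperone gene hsp-110 at 1.04, the fatty acid desaturase genes fat-5 at 1.42 and fat-6 at 0.63, and the lipid droplet gene plin-1 at 0.73. Their blocked adjusted p values were 0.0031, 0.0093, 0.0094, 0.0093, 0.013 and 0.046, and in the fit without the block their adjusted p ran from 0.067 to 1. The brightest probe set of hsp-110, at 0.77, did not pass with the block, adjusted p = 0.096, nor did the other probe sets of plin-1, at 0.32 and 0.42, adjusted p = 0.57 and 0.60. In the HLH strain the blocked count was 6, with 5 higher and 1 lower at code 2. It was 20, with 13 higher and 7 lower, when the array titled 2_2 (2) was kept and placed in set 3. With the inducible heat shock list at estimated correlation, the blocked adjusted p in the marker strain was 0.053, and with the ER stress list it was 0.044.

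**Figure D1:**
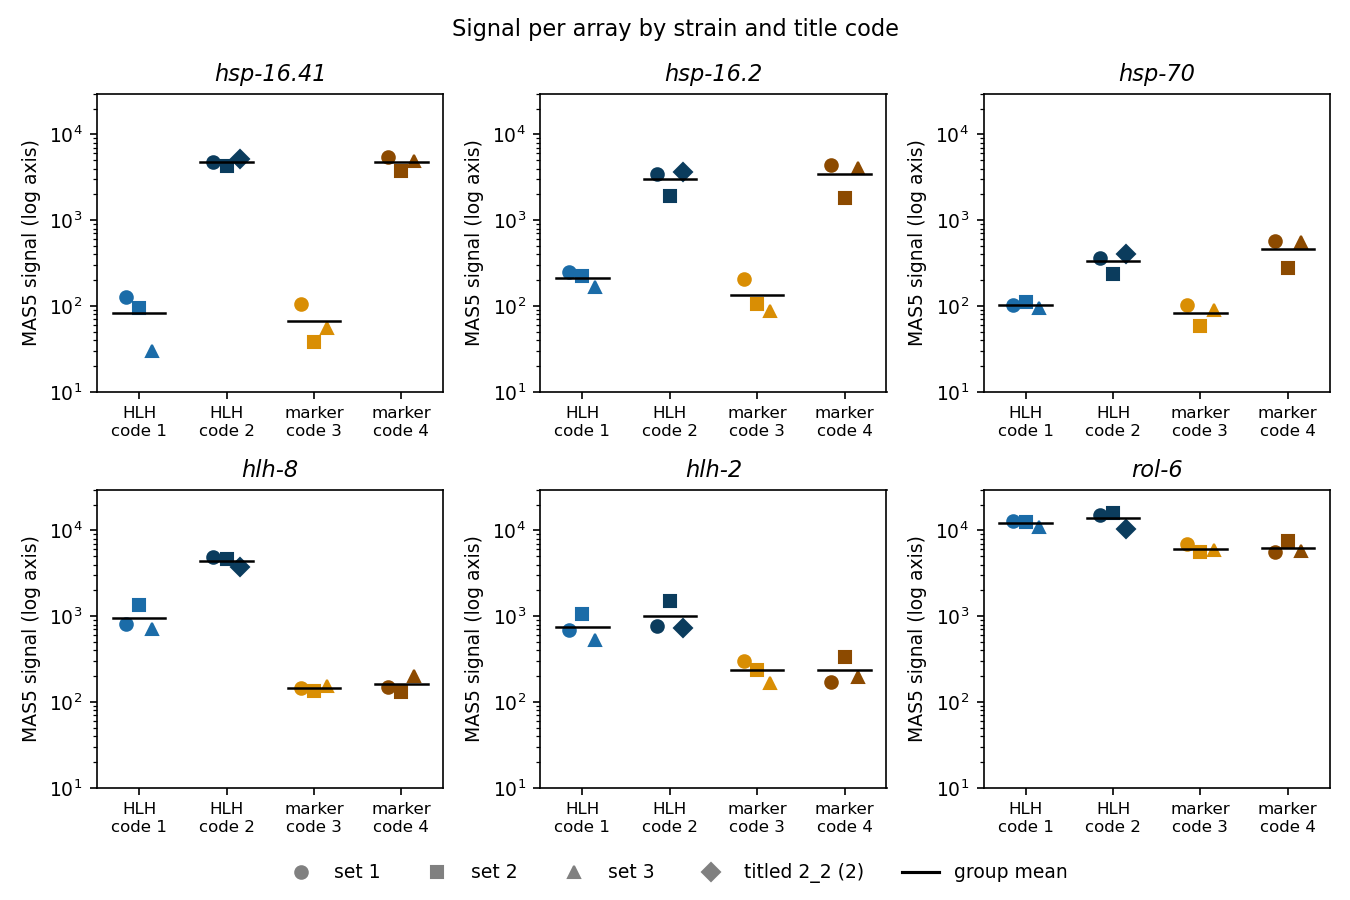
MAS5 signal on a log axis of hsp-16.41, hsp-16.2, hsp-70, hlh-8, hlh-2 and rol-6 on each of the 12 arrays, by strain and title code. Symbols give the set number, a diamond marks the array titled 2_2 (2), and the horizontal line is the group mean over 3 arrays. The mean of hsp-16.41 was 84 and 66 at codes 1 and 3 and 4756 and 4718 at codes 2 and 4, while hlh-8 was at 4444 at code 2 and 161 at code 4.

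Across both strains, 4 probe sets were called in both within-strain comparisons, those of hsp-16.41 and hsp-16.2 and 2 probe sets of several genes, all higher at codes 2 and 4. Independent lists of 5 and 7 among 12328 probe sets would share 0.00284 on average. These comparisons had no array in common. Pearson's r between their log2 differences across probe sets was 0.40, and 0.29 without the 8 probe sets called in either comparison. It describes probe sets, which are not independent replicates.

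The third comparison, of the HLH strain with the marker strain over both codes, does not depend on which code was heat shocked. The gene hlh-8 had the largest log2 difference among the named genes that were higher in the HLH strain, at 3.74 ± 0.17 (SE), a 13.4-fold difference with an adjusted p of 1.3e-07. Its partner hlh-2 was 3.67-fold higher, 1.88 ± 0.25 (SE) on the log2 scale, adjusted p = 0.0014, and a further probe set of hlh-2 was higher by 1.31, adjusted p = 0.012. The collagen gene rol-6 was 2.07-fold higher, 1.05 ± 0.13 (SE), adjusted p = 0.00078, although both strains carried pRF4. The log2 difference was -0.13 ± 0.18 (SE) for egl-15 and -0.04 ± 0.21 (SE) for arg-1, and neither passed, with adjusted p of 0.81 and 0.95.

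Outside the transgene list, lea-1, a late embryogenesis abundant protein gene, was 6.03-fold higher in the HLH strain (log2 2.59 ± 0.22 SE, adjusted p = 0.00017). All 5 of its tested probe sets were higher, by 1.44 to 2.59. The beta-tubulin gene tbb-6 was 3.30-fold, the neuropeptide receptor gene npr-16 3.26-fold, the zona pellucida domain gene dex-1 3.19-fold and F35F10.5 2.78-fold higher. A further called probe set of dex-1 differed by a log2 of 3.46, adjusted p = 0.00044, and one of npr-16 by 2.48, adjusted p = 0.00096, more than the named ones, at 1.67 and 1.70. The gene eat-20 was 3.59-fold higher with one probe set, but its brighter probe set differed by a log2 of 0.40 and did not pass, adjusted p = 0.10, blocked 0.0255. The first probe set lost its call without the filter and without the 4 set 2 arrays, adjusted p = 0.075 and 0.088. The nuclear receptor gene nhr-155 and the antimicrobial peptide gene cnc-6 were 3.09-fold and 2.94-fold higher, with adjusted p of 0.045 and 0.033. Among single arrays left out, the call of nhr-155 was kept only without marker code 4 replicate 2 or 3 and that of cnc-6 only without marker code 4 replicate 1, 2 or 3; leaving out any other single array gave adjusted p of 0.052 to 0.11 and 0.051 to 0.096. Both calls were also lost without the filter, adjusted p = 0.14 and 0.11, with the array titled 2_2 (2) averaged with its namesake, 0.077 and 0.064, and without the set 2 arrays, 0.093 and 0.075.

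Among the genes lower in the HLH strain, ZC196.5 was at the floor on all 6 HLH arrays, so its log2 difference of -4.01 ± 0.39 (SE) is a bound, with mean signals of 269 and 296 (n = 3) at codes 3 and 4 and 5 and 6 at codes 1 and 2, and an adjusted p of 2.0e-04 in limma. The phospholipase C gene plc-1 was lower by a log2 difference of -3.74 ± 0.35 (SE), adjusted p = 0.00017, with 1 of 3 arrays at the floor at each HLH code. Its 3 tested probe sets differed by -3.07 to -3.78, the last with 2 of 3 arrays at the floor at each HLH code. The genes C23G10.11 and T22F3.11 were lower by log2 differences of -3.76 ± 0.59 (SE) and -3.20 ± 0.47 (SE). The differences were -2.21 for C35C5.8, -2.15 for ZK512.7, -2.07 for F46C5.1 and -1.77 for F43C11.3. The C-type lectin genes clec-61 and clec-82 were lower by -1.83 and -1.77. Further called probe sets were at -3.89 for T22F3.11, -1.93 for ZK512.7 and -1.47 for C35C5.8. Without the filter the adjusted p of C35C5.8 was 0.051. For 5 of these genes the size depended on the set. With code 1, the HLH code that every set has, set against the mean of codes 3 and 4 within sets 1, 2 and 3, the difference was -4.66, -5.28 and -2.27 for C23G10.11 and -4.06, -4.56 and -1.19 for T22F3.11. It was -2.40, -3.48 and -1.03 for C35C5.8, -2.12, -3.02 and -1.13 for F46C5.1 and -2.22, -2.37 and -0.70 for clec-82. All 20 named genes kept their direction in each set in this measure. The naming rule fixed that in advance, since it asked for no overlap between the arrays of the strains. The measure was chosen after the data were seen and has 1 HLH array per set and no test.

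In limma's test, 335 probe sets differed between the strains, 139 higher and 196 lower in the HLH strain, and 115 of them at least 2-fold, while 1983 had an unadjusted p under 0.05. With the set number as a block and the array titled 2_2 (2) left out, 1731 differed, 836 higher and 895 lower, and all 335 were among them. Without the 4 arrays of set 2, an alternative chosen after the data were seen, 195 differed and 157 of them were among the 335. The count was 186 without HLH code 1 replicate 1, 180 without HLH code 2 replicate 1, 189 without HLH code 1 replicate 2, 182 without HLH code 2 replicate 2, 220 without marker code 4 replicate 1 and 219 without marker code 4 replicate 3.

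**Figure D2:**
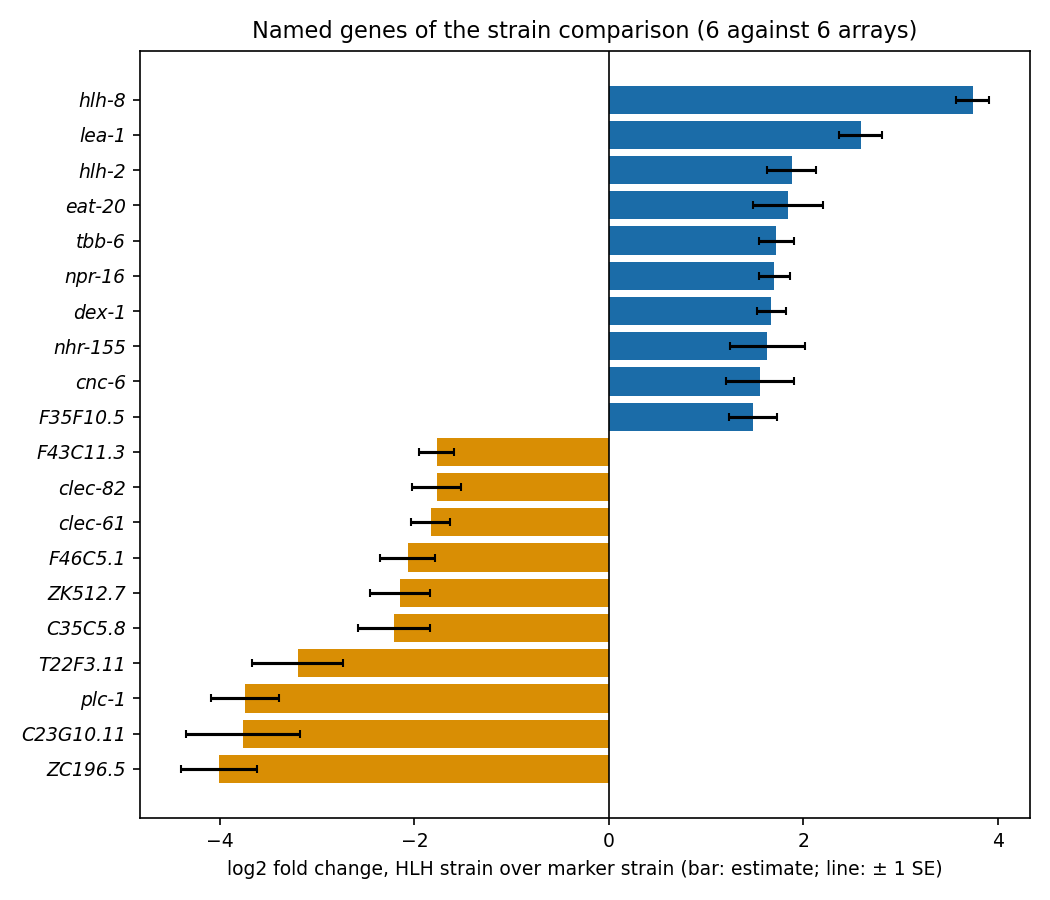
Log2 fold change of the HLH strain over the marker strain for the 20 genes named by rule, 10 higher and 10 lower, from 6 arrays against 6. Bars give the estimate and lines 1 standard error to each side. The estimates ran from 3.74 for hlh-8 to -4.01 for ZC196.5, the latter a lower bound in size because all 6 HLH arrays were at the floor.

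Of the 29 gene lists, the transgene list rose between strains in 3 of 4 genes, adjusted p = 3.7e-06, and adjusted p = 0.057 with an estimated correlation. Of 29 immune response genes 4 rose and 3 fell, and the list as a whole did not pass, adjusted p = 0.83. Those that rose included the caenacin genes cnc-2 at 1.44 ± 0.15 (SE) and cnc-4 at 0.98 ± 0.19 (SE) and irg-2 at 1.21 ± 0.24 (SE), and those that fell included the lectin gene clec-60 at -1.67 ± 0.33 (SE) and irg-1 at -0.94 ± 0.20 (SE). Of 28 lipid metabolism genes 3 fell, the acyl-CoA synthetase gene acs-2 at -1.06 ± 0.23 (SE), lbp-1 at -0.61 ± 0.13 (SE) and the desaturase gene fat-3 at -0.50 ± 0.12 (SE). That list lay lower with adjusted p = 2.0e-04, and adjusted p = 0.057 with an estimated correlation, and 2 of its genes rose and 9 fell when adjusted over the list alone, as did 2 and 11 over all probe sets with the block. Of 25 oxidative stress and detoxification genes 2 fell, cyp-34A9 at -1.14 and ugt-13 at -0.68, and the list had adjusted p = 0.061. Of 76 collagens col-113 rose by 1.06, while col-39 and col-147 differed by -0.67 and -0.48, and the list had adjusted p = 0.063. Single members fell in the lists of cell cycle and replication (mcm-7 at -0.67, list adjusted p = 0.65), oogenesis and germline (cpg-2 at -1.18, list adjusted p = 0.89), the F-box family (fbxa-72 at -0.69) and ubiquitin ligase adaptors (skr-4 at -0.83, list adjusted p = 0.10). In the hypodermis and cuticle list 1 of 29 genes, rol-6, rose, and the list had adjusted p = 0.80. Of 17 bHLH factors only hlh-8 and hlh-2 passed in this comparison, and the list had adjusted p = 0.73.

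Several tissue and stage lists shifted with the preset correlation only. The moulting list lay higher in the HLH strain, median 0.16 over 23 genes, adjusted p = 0.0020, and adjusted p = 0.43 with an estimated correlation. Of its genes fbn-1, a fibrillin-like gene, rose by 0.86 ± 0.16 (SE), and with the block 7 rose. The intestine list lay lower, median -0.20 over 24 genes, adjusted p = 0.00069, and adjusted p = 0.50 with an estimated correlation. No intestine gene passed over all probe sets, 6 fell when adjusted over the list alone, among them the intermediate filament gene ifb-2 at -0.43 ± 0.11 (SE) and far-2 at -0.50 ± 0.13 (SE), and 11 fell with the block. The body wall muscle list lay lower, median -0.14 over 31 genes, adjusted p = 0.0019, and adjusted p = 0.51 with an estimated correlation. No body wall muscle gene passed, the myosin light chain gene mlc-1 and the tropomyosin gene lev-11 each being at -0.28 ± 0.08 (SE), with the block 10 fell, these included, and after quantile normalization the list had adjusted p = 0.22. The histone list lay lower, median -0.19 over 22 genes, adjusted p = 0.00038, and adjusted p = 0.50 with an estimated correlation, with his-1 at -0.51 ± 0.13 (SE) and his-64 at -0.54 ± 0.15 (SE). The ribosomal protein list lay lower by a median of -0.12, adjusted p = 5.8e-07, with adjusted p = 0.74 with an estimated correlation, and it turned higher after quantile normalization without passing, adjusted p = 0.098. The translation factor and constitutive chaperone lists each lay higher by a median of 0.19, adjusted p = 0.017 and 0.022, with adjusted p = 0.74 and 0.61 with an estimated correlation. The F-box family lay lower, median -0.06 over 48 genes, adjusted p = 0.032, and adjusted p = 0.63 with an estimated correlation. The proteasome and ubiquitin list had adjusted p = 0.22, and lay higher with adjusted p = 0.0064 with the block, 0.72 with an estimated correlation.

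The remaining lists did not pass between strains. The adjusted p was 0.066 for known Twist/E targets, of which hlh-8 rose, and 0.30 for M lineage and mesoderm regulators, of which 0 of 14 passed. It was 0.57 for small and inducible heat shock proteins, 0.61 for ER stress, 0.57 for mitochondrial chaperones, 0.16 for metal response, 0.65 for pharynx, 0.73 for neurons, 0.73 for sperm and 0.65 for embryo. No member of these last 8 lists passed over all probe sets without the block. When adjusted over the list alone, 1 gene fell in each of the metal response, sperm and embryo lists. Further genes also passed in that way in lists described above. The counts were then 4 higher and 4 lower for immune response, 1 and 3 for detoxification, 0 and 6 for the F-box family, 0 and 2 for histones, 2 and 0 for moulting, 1 and 1 for hypodermis and cuticle, and 2 and 1 for bHLH factors.

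Each HLH code was also set against each marker code, since the matching of codes is unstated. Code 2 against code 4 gave 49 called probe sets, code 1 against code 3 gave 54, code 2 against code 3 gave 99 and code 1 against code 4 gave 90, and with the block the counts were 480, 540, 580 and 1159. The gene hlh-8 was higher in the HLH strain in all 4, by log2 differences of 4.81, 2.68, 4.94 and 2.54, each ± 0.24 (SE). For hlh-2 the differences were 2.08, 1.67, 2.05 and 1.70, each ± 0.35 (SE), of which the comparison of code 1 with code 3 did not pass, adjusted p = 0.072, blocked 0.0013. For rol-6 they were 1.12, 0.98, 1.15 and 0.95, each ± 0.18 (SE), and all 4 passed. In none of the 4 did egl-15 or arg-1 pass, the smallest adjusted p being 0.80 and 0.93. The gene ZC196.5 was lower in the HLH strain in all 4, by at least 17.1-fold, 15.2-fold, 15.2-fold and 17.1-fold in the order above. The genes hsp-16.41 and hsp-16.2 were called where codes 2 and 3 or codes 1 and 4 were compared, with hsp-16.41 at 6.28 ± 0.45 (SE) and -6.03 ± 0.45 (SE) and hsp-16.2 at 4.55 ± 0.38 (SE) and -3.92 ± 0.38 (SE). The counts moved by over 1.5 times when single arrays were left out. For code 2 against code 4 this was 15 and 17 without HLH code 2 replicates 1 and 2, and 16, 29 and 20 without marker code 4 replicates 1, 2 and 3. For code 1 against code 3 it was 18, 20 and 30 without HLH code 1 replicates 1, 2 and 3, and 22 without marker code 3 replicate 1 or 2. For code 2 against code 3 it was 40 and 39 without HLH code 2 replicates 1 and 2, and 61, 61 and 54 without marker code 3 replicates 1, 2 and 3. For code 1 against code 4 it was 24, 34 and 55 without HLH code 1 replicates 1, 2 and 3, 35 and 44 without marker code 4 replicates 1 and 3, and 56 and 146 without marker code 3 replicates 1 and 2.

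A last comparison asked whether the code difference itself differed between strains, whichever way the codes are matched. For hlh-8 the code difference was 2.27 ± 0.24 (SE) in the HLH strain and 0.14 ± 0.24 (SE) in the marker strain. Its sizes differed by 2.13, with limma's adjusted p = 1e-04 when adjusted over the list alone, that of transgene genes, and adjusted p = 0.32 over all probe sets. No probe set passed over all 12328 in limma, and 11 had an unadjusted p under 0.05. Without HLH code 1 replicate 2, hlh-8 passed with a size difference of 2.41, adjusted p = 0.018, and over all alternatives its adjusted p ran from 0.018 to 1. The test recovered 5 of 100 simulated 2-fold and 73 of 100 simulated 4-fold differences. The simulated noise was independent, with no set difference, so these shares need not hold for the real arrays. The size difference of hlh-8, 4.37-fold, did not pass over all probe sets. A count of 0 therefore leaves differences of that size and smaller ones undetected.

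With code 2 matched to code 4, 0 probe sets passed in limma and 87 had an unadjusted p under 0.05. That is fewer than chance alone would give on average, so the count of 0 can miss differences. In this matching the code difference of several lists differed between strains with the preset correlation, and that of none with an estimated correlation. It was higher in the HLH strain for the transgene and known target lists, adjusted p = 7.5e-05 and 0.00058, and adjusted p = 0.065 for each with an estimated correlation. In both lists 1 gene, hlh-8, passed when adjusted over the list alone, while the known target arg-1 was at -0.11 ± 0.41 (SE), hlh-2 at 0.40 ± 0.50 (SE), rol-6 at 0.14 ± 0.26 (SE) and egl-15 at 0.34 ± 0.36 (SE), each with an adjusted p of 1. It was also higher for ribosomal proteins, adjusted p = 0.035, and adjusted p = 0.95 with an estimated correlation, and turned lower after quantile normalization, adjusted p = 0.86. It was lower for inducible heat shock proteins (adjusted p = 0.038), constitutive chaperones (0.029), cell cycle and replication (0.0016), oogenesis and germline (0.0065) and sperm (0.027), with adjusted p = 0.52, 0.67, 0.52, 0.67 and 0.67 with an estimated correlation. With the block, constitutive chaperones, cell cycle and sperm did not pass, adjusted p = 0.12, 0.10 and 0.24, and hypodermis and cuticle turned higher and passed, 0.97 without the block and 0.038 with it, and 0.66 with the block and an estimated correlation.

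With code 2 matched to code 3, 13 passed, 12 higher and 1 lower, and 54 passed with the block, 32 higher and 22 lower. These 13 included hsp-16.41 at 12.32 ± 0.64 (SE), hsp-16.2 at 8.47 ± 0.54 (SE), hsp-70 at 4.12 ± 0.46 (SE) and hlh-8 at 2.40 ± 0.33 (SE). They also included hsp-4 at 2.95 ± 0.39 (SE), fat-5 at 2.55 ± 0.42 (SE), hsp-17 at 1.80 ± 0.27 (SE) and dnj-13, a DnaJ-type co-chaperone gene, at -1.59 ± 0.22 (SE), which were chosen for naming after their values were seen. The values of hlh-2, rol-6, egl-15 and arg-1 were 0.35 ± 0.50, 0.20 ± 0.26, 0.00 ± 0.36 and 0.15 ± 0.41 (SE), each with an adjusted p of 1. Under that matching the value is the sum of the 2 within-strain differences, so genes with the same sign in both stand out. The inducible heat shock and ER stress lists were shifted upwards, adjusted p = 3.0e-11 and 2.2e-08, and adjusted p = 0.0096 for each with an estimated correlation. With the block and an estimated correlation ER stress passed, adjusted p = 0.022, and inducible heat shock did not, adjusted p = 0.15. Other lists passed with the preset correlation alone, and in the transgene and known target lists hlh-8 was the only gene called. Shifted upwards were transgene genes (adjusted p = 0.0088), known targets (0.010), constitutive chaperones (4.6e-05), lipid metabolism (0.0015) and ribosomal proteins (2.2e-10), with adjusted p = 0.18, 0.13, 0.18, 0.085 and 0.73 with an estimated correlation, and the ribosomal list did not pass after quantile normalization, adjusted p = 0.83. Shifted downwards were translation factors (adjusted p = 0.040), cell cycle and replication (0.010) and oogenesis and germline (0.010), with adjusted p = 0.82, 0.47 and 0.65 with an estimated correlation. With the block, known targets, translation factors and cell cycle did not pass, adjusted p = 0.11, 0.28 and 0.10. Hypodermis and cuticle, collagens and neurons passed with the block alone, adjusted p = 0.0029, 0.0026 and 0.032, and adjusted p = 0.59 for each with an estimated correlation.

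The arrays also differed by set number. The 4 arrays of set 2, 1 per code, lay apart from the other 8, the array titled 2_2 (2) being among the latter. The tests of set 2 against sets 1 and 3 left out the array titled 2_2 (2). In them 5202 probe sets differed, 3058 higher and 2144 lower in set 2. Of 74 ribosomal protein genes 71 were lower, and the list's median was -0.32, and -0.03 after quantile normalization. Of the other lists above that shifted between strains, intestine had 1 of 24 genes higher and 12 lower in set 2, body wall muscle 3 and 17 of 31, translation factors 0 and 20 of 35, and constitutive chaperones 5 and 12 of 23. Histones had 0 higher and 4 lower of 22, moulting 4 and 5 of 23, lipid metabolism 6 and 6 of 28, the F-box family 10 and 2 of 48, and transgene genes 2 and 0 of 4. After quantile normalization the median set difference went from -0.25 to -0.09 for intestine, from -0.24 to -0.06 for body wall muscle, from -0.30 to -0.22 for translation factors, from -0.32 to -0.22 for constitutive chaperones, from -0.22 to -0.30 for histones and from 0.26 to 0.31 for transgene genes. It changed sign for moulting, from 0.02 to -0.04, for lipid metabolism, from -0.04 to 0.08, and for the F-box family, from 0.04 to -0.03.

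**Figure D3:**
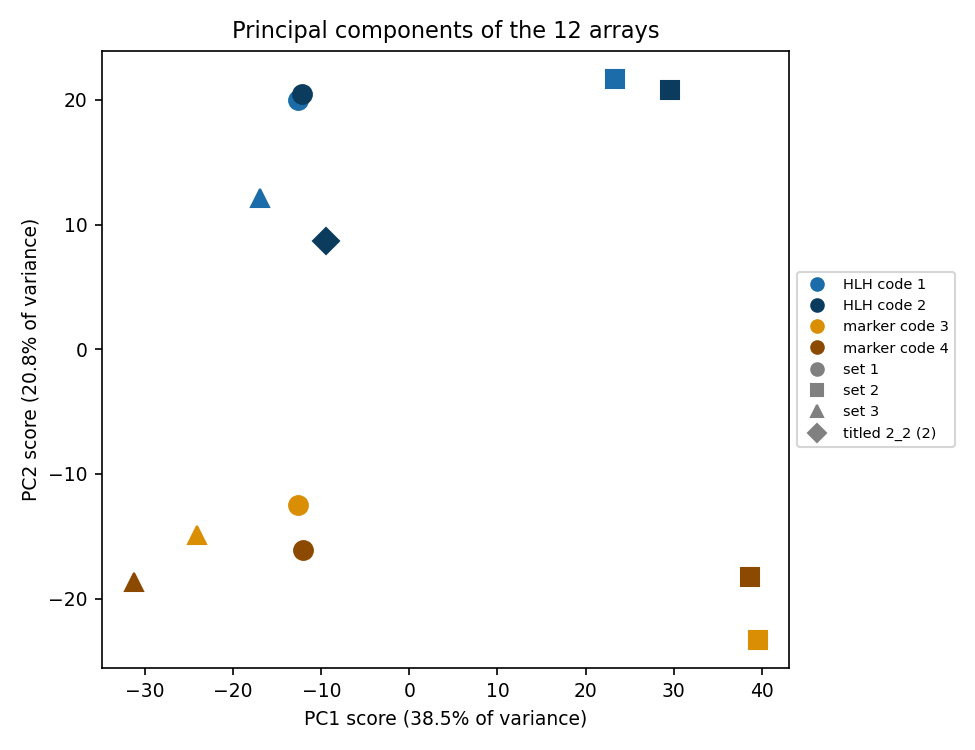
Scores of the 12 arrays on the first and second principal components of the log2 values of the 12328 tested probe sets, with colour for strain and code and symbol for set number. The first component held 38.5% of the variance and set apart the 4 arrays of set 2, and the second held 20.8% and set apart the strains.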

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

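The transgene gene hlh-8 had a code difference that was larger in the HLH strain than in the marker strain by 2.13 on the log2 scale, a difference between strains that was tested directly, by a test that does not depend on how the codes are matched. Its p was 2.6e-05 in limma, with adjusted p = 1e-04 over the 4 transgene genes and 0.32 over all 12328 probe sets, and the latter ran from 0.018 to 1 over the alternatives. Signals of hlh-8 were 958 and 4444 at codes 1 and 2 and 144 and 161 at codes 3 and 4. The HLH strain carried an hlh-8 construct and the marker strain did not, which is a difference of the design.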

How the results depend on the processing

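Leaving out the 4 arrays of set 2 was chosen after the data were seen, and the other alternatives were not. Counts that moved by over 1.5 times are given by setting. With no filter, the counts were 4 for code 4 against code 3 and 7 for the interaction with code 2 matched to code 3. For code 2 against 4, 1 against 3, 2 against 3 and 1 against 4 they were 22, 17, 62 and 34, with more probe sets tested. With only the compared groups in the fit, they were 4 for code 4 against code 3, and 14, 35 and 49 for code 2 against 4, 1 against 3 and 2 against 3, with fewer arrays to estimate the spread.

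With the set number as a replicate block and the array titled 2_2 (2) left out, the counts were 19 for code 4 against code 3, 1731 between strains, 54 for that interaction, and 480, 540, 580 and 1159 for the comparisons of single codes in the order above. With that array in set 3 they were 20 for code 2 against code 1, 17, 1663, 70, 409, 451, 584 and 1015, and with it in set 2 they were 13, 1195, 28, 220, 249, 394 and 563 from code 4 against code 3 on. Between strains the block also called further members of several lists, such as 6 higher and 7 lower immune response genes and 5 higher and 10 lower collagens. Apart from these counts, such list members and the blocked values printed beside the results, the block without that array changed no other call over all probe sets, nor any other list call, reported in the text. With that array averaged with its namesake, the counts were 30 for code 2 against 4 and 59 for code 2 against 3. Without the set 2 arrays they were 195 between strains, 157 of them among the 335, and 30, 18 and 63 for code 2 against 4, 1 against 3 and 2 against 3. The cause was not tested for the last 2 settings.

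With single arrays left out, the count ranged from 5 to 6 for code 2 against 1, 4 to 8 for code 4 against 3, 180 to 315 between strains, and 0 to 1 for the difference under either matching. It ranged from 0 to 1 and 10 to 13 for the interactions with code 2 matched to codes 4 and 3, and from 15 to 63, 18 to 67, 39 to 107 and 24 to 146 for single codes. The ribosomal protein list reversed after quantile normalization between strains, adjusted p = 0.098, and in the interaction with code 2 matched to code 4, 0.86. In the latter the hypodermis and cuticle list reversed with the block, 0.038. The cause was not tested for these. Of the other list results under alternatives 515 kept their side of the threshold, 44 lost a call and 18 gained one. Of those for named genes 429 were the same and 16 lost a call, and with single arrays left out 377 were the same, 30 lost a call and 1 gained one. Low signals limit what can be seen, and probe sets near the floor have only bounds.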

Other observations

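The tests of neighbouring genes, of other probe sets of a gene, of RNA integrity, of the set of the array titled 2_2 (2), and the splits for the interaction with code 2 matched to code 4 and for either matching were chosen only after the result was seen. Set 2, with 1 array per code, was set against sets 1 and 3, with the array titled 2_2 (2) left out. The genes try-12, C02G6.1 and math-35 were higher in set 2 by 3.89, 3.40 and 3.24 on the log2 scale. The genes rpa-4 and drh-2 were 9.06-fold and 7.13-fold higher, with mean signals of 1238 against 151 and 3059 against 470. Lower in set 2 were tag-164 by a log2 difference of -2.33, C53C7.5 by -2.23, the collagen gene col-150 by -1.81 and the neuropeptide gene flp-7 by -1.43. These genes were chosen after their values were seen.

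Of 19 sperm genes 11 were lower in set 2 and 1 higher, with a median of -0.41, and -0.55 after quantile normalization. Of 36 neuron genes 18 were lower and 4 higher, of 29 oogenesis and germline genes 12 and 3, and of 76 collagens 29 and 2. Their medians were -0.30, -0.28 and -0.22, and -0.27, -0.40 and -0.15 after quantile normalization. No list shift passed with an estimated correlation, the lowest adjusted p being 0.26.

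The genes that differed between strains outside the transgene list are a pattern to weigh. For genes with a further tested probe set the tables argue against single faulty probe sets. Of 64 further probe sets 63 had the same direction, 98.4% (exact 95% interval 91.6 to 100). The interval takes probe sets as independent, although some genes have several. The called genes numbered 277, so most had no further tested probe set, and for those the question stays open. For the called genes together the tables also argue against a response that follows the hlh-8 level, which was 4.81-fold higher at code 2. Their median code 2 minus code 1 difference, in the direction of the strain difference, was -0.02, against a median strain difference of 0.79. By set it was 0.02, 0.02 and -0.04, the last with the array titled 2_2 (2) placed in set 3, although its set is uncertain. The genes were called on the mean over both codes, which can miss genes raised at code 2 alone. For such genes these values say nothing. Nor do these values cover a response already complete at code 1, where hlh-8 was above codes 3 and 4 by log2 differences of 2.68 and 2.54. Of the called genes outside the transgene list, 263 had a place in the gene order, and 15.2% of them had a called neighbour. In 10000 random lists the median was 5.3% and the 99th percentile 10.6%, and for genes ranked by the set difference the share was 6.5%. Linked stretches of the genome that differ between the strains may therefore be a source, as a hypothesis, while clusters of related or co-regulated neighbours stay open and were not tested separately, as does a lasting effect of the constructs.

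For the set 2 arrays, an intensity-dependent difference between arrays is argued against as the whole cause, since 75.6% of the 4942 probe sets called between sets were still called after quantile normalization. RNA integrity cannot be told apart: the Gapdh 3' to 5' ratio was higher in set 2 in 4 of 4 groups and that of actin in 3 of 4, with 1 array per group. No biological explanation was tested, because the labels give no difference between sets.

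The array titled 2_2 (2) may carry a wrong set number in its title. Its score on the axis of set 2 against sets 1 and 3 was -0.16, against 0.53 for the array titled 2_2 and -0.21 for code 2 of set 1. On the axis of set 3 against set 1 it scored 0.01, nearer to the -0.40 to -0.12 of the set 1 arrays, with -0.12 for code 2, than to the 0.48 to 0.78 of the set 3 arrays. Both axes were drawn from the arrays of codes 1, 3 and 4 alone, so scores of code 2 arrays do not compare evenly with theirs. Deviations of the array titled 2_2 (2) correlated with the arrays of codes 1, 3 and 4 at 0.54, 0.23 and 0.23 in set 3. The values were 0.05, 0.19 and 0.24 in set 1 and -0.51, -0.31 and -0.35 in set 2. By these values alone set 1 or set 3 stays open. By the titles, set 1 already has an array of code 2 and set 3 has none, which points to set 3. The array titled 2_2 (2) is not a copy of the array titled 2_2, with a Spearman's rho of 0.933 and 0.04% identical values.

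Other groupings of the arrays were tried for each count. Between strains, 3 of 100 shuffles gave at least as many probe sets as the real 335, the real one included. That is a share under 0.05, so chance is unlikely but not excluded, and the highest other count was 698. The 2 others, with 698 and 656, kept all 6 HLH arrays on one side and so repeat the strain division, and the highest that broke it up was 106. Within sets, 1 of 100 shuffles gave as many, the highest other being 324. For the interaction with code 2 matched to code 3, 3 of 100 splits gave at least the real 13, and the highest other was 680. The 2 larger ones, 680 and 452, had all 4 set 2 arrays on one side. Of the splits drawn 8 had that arrangement, these 2 included, with a median of 0 called, and the splits with another arrangement called 0 at most. The arrangement of the sets was thus shared by both large splits but was not enough for a large count, and with the set number as a block the count was 54. For the interaction with code 2 matched to code 4 and for either matching, 100 of 100 splits gave at least the real 0, which any split does, so these say nothing about chance, and the highest others were 1088 and 0. The comparisons of 3 against 3 arrays have 10 splits, too few for a share under 0.05. In each, 1 of 10 gave as many as the real count, which was 5 for code 2 against 1, 7 for code 4 against 3, and 49, 54, 99 and 90 for single codes between strains, and the highest other was 0 in each.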
